A study of Danio rerio with 50 samples.

How the data were processed

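The arrays compared liver RNA of adult male zebrafish kept in water with estradiol, or untreated, with a common pool of liver RNA from wild-type males and females. Per the labels' protocols, total RNA was extracted with Trizol, and 10 µg of each fish sample was copied into DNA with Cy5 while the pool carried Cy3. All 50 arrays had the same dye orientation, so a dye effect stays in every ratio and cancels only in differences between groups. The groups came from the titles: 8 and 7 untreated samples at 24 and 96 h, and 6, 6 and 6 samples of 0.5, 5 and 50 µg/L at 24 h and 6, 4 and 7 at 96 h. The descriptions of 6 of the 7 samples of 50 µg/L at 96 h give a time 1 h longer than their titles, and those of 5 µg/L at 96 h count 6 replicates, of which 4 are held. The labels call them biological replicates but do not say whether fish of 1 group shared a tank, so p-values measure the spread between these samples.

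The value table that the authors deposited holds log2 ratios of the fish sample over the reference pool, 1 column per array, with array medians from -0.04 to 0.03. The method of normalization and the image software are not given in the sources used here. For the 35 treated arrays the deposited scanner files also hold, per the file headers, the brightness (intensity) of each spot and of its local background in both channels, and the authors' normalized ratio. The value table equalled the value column of those files exactly, and correlated with the raw log2 ratio of Cy5 over Cy3 at r of 0.906 to 0.989 across probes, which settled its direction and scale. Scanner files of the 15 control arrays were not analysed here, so the signal of the controls is unknown, and comparisons with controls rest on the authors' log2 ratios.

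Of 23232 probes, 457 had no value on any array, and 22046 with a value on at least 3 arrays of each of the 8 groups were tested; 14677 of the probes had a value on every array. Among tested probes 2.28% of values were missing. The annotation gave 1 gene symbol for 11724 probes and none for 11508. Of its 10118 distinct symbols, 3011 are current in the table of the GRCz12tu assembly, 6996 were updated through synonyms, and 111 that are synonyms of several genes were kept. The tested probes covered 9164 named genes, of which 1736 had more than 1 probe, and 10502 tested probes have no name here. A gene with several probes is represented by the one with the highest mean Cy3 brightness over the treated arrays. No genome positions were used.

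Each array was centred on its median, and 8 group means were fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; the package data.table, version 1.17.8, to read files; matplotlib 3.10.9 for plots). Each dose was compared with the controls of its own time; the difference of that effect between 96 and 24 h and the difference between the control groups were tested in the same fit. The direct comparison of 50 with 0.5 µg/L used only treated arrays, starting from scanner brightness with normexp background correction (offset 50) and loess within arrays. P-values were adjusted by the Benjamini-Hochberg method over all tested probes, and an adjusted p under 0.05 counts as a change. Printed changes are differences of log2 ratios ± SE of the fit; SDs appear only in the plot of vtg3 and esr1. A spot was taken as above background where over 50% of its pixels were, per the file headers, and as saturated at the top of the scanner's range; where all arrays of a treated group were saturated in Cy5 the fold of a rise is a lower bound ("at least") and a fall is not established.

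For 37 lists of genes with known functions or of cell type markers, limma's camera compared the genes of a list with all other named genes, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists and the 6 estradiol comparisons; fry was run beside it. Missing values were replaced by the group mean for these tests only. Member counts are given over all tested probes and, where stated, adjusted over the list alone. The groups, tests, lists and other settings were fixed before the data were examined, as was the rule for named genes: the up to 8 largest rises and falls past the threshold in each estradiol comparison, and up to 4 in each other comparison, with a log2 size over 0.58 where so many pass. Every vitellogenin and estrogen receptor, and the up to 4 members with the smallest p of each list described, were also named. Genes known only by a clone name were passed over.

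The fit was tested on simulated data with 200 of 22046 probes changed. At 50 µg/L and 96 h it recovered 14.9%, 80.6% and 97.0% of probes changed by 0.5, 1 and 2 on the log2 scale, and at 0.5 µg/L and 24 h 20.9%, 79.1% and 95.5%. A stricter pass mark for changes of 2 was dropped after the difference between times at 5 µg/L recovered 89.4%, just short of it. No simulated change was called in the wrong direction. Unchanged probes made up 12, 6 and 2 of 142, 137 and 124 calls at 0.5, 5 and 50 µg/L at 24 h. At 96 h they made up 4, 3 and 11 of 135, 118 and 139. Far more probes were called in the real data at 50 µg/L and 96 h (18.0%) than were changed here, so recovery there may differ. The number of arrays limits the precision: the median SE was 0.19 for 50 µg/L at 96 h and 0.29 for the difference between times at 5 µg/L.

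Alternatives were no centring, quantile normalization, other filters on missing values and dim probes, only the arrays of a contrast, trended and robust eBayes, array weights, replicate numbers as a block, controls of both times pooled, each array left out in turn, other background and within-array corrections for the comparison of doses, and the mean over a gene's probes. After seeing the data, analyses without 5 arrays of low signal, of list shifts without 1 array that stood apart, of list shifts in the differences between times, of the difference between times at 50 µg/L without 1 array of each time, of the position of each 50 µg/L array between the times, and of lists adjusted over 1 comparison were added. No batch of slides, print runs or scans was tested, because the files used here give none.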

Results

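Liver RNA of adult male zebrafish (Danio rerio), a small freshwater fish, was measured on 2-colour oligonucleotide arrays after the fish had lived in water with estradiol. Estradiol is the estrogen that drives yolk protein synthesis in the liver of egg-laying females. Males received 0.5, 5 or 50 µg/L for 24 or 96 h. Untreated males were sampled at both times. There were 8 control arrays at 24 h and 7 at 96 h, 6 arrays for each dose at 24 h, and 6, 4 and 7 arrays for 0.5, 5 and 50 µg/L at 96 h. Each array gave a log2 ratio of the fish sample over a reference pool of male and female liver for 17483 to 22746 of 23232 probes.

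Arrays correlated with the mean of the rest of their group at r of 0.592 to 0.951 across probes, which are not independent replicates. The median Cy5 brightness of the treated arrays ranged from 174 to 921 scanner units. Less than 60% of Cy5 spots lay above background on 5 arrays: 50 µg/L at 24 h replicates 3 (52.9%), 4 (44.2%) and 5 (38.5%), and 50 µg/L at 96 h replicates 3 (26.4%) and 4 (57.7%). Of 35 treated arrays 4 correlated better with the same dose at the other time than with their own group: 50 µg/L at 96 h replicate 4 (0.925 against 0.862), 50 µg/L at 24 h replicate 5 (0.890 against 0.847), 0.5 µg/L at 24 h replicate 2 (0.634 against 0.592) and 5 µg/L at 24 h replicate 3 (0.821 against 0.814). The brightness of the control arrays was not analysed here. Changes below are log2 differences from the controls of the same time ± SE from limma's fit, and adjusted p-values are limma's. Genes are ranked among named genes by measured value.

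The yolk precursor gene vtg3 was the strongest named response in most comparisons. At 24 h its representative probe (5466044) rose by 4.50 ± 0.26 at 0.5 µg/L, a 22.6-fold change, by 6.81 ± 0.26 at 5 µg/L and by 7.29 ± 0.26 at 50 µg/L (n = 6 treated and 8 control arrays each), with its Cy5 spot saturated on none, 4 and 3 of the 6 treated arrays. At 96 h it was at least 130-fold higher at 0.5 µg/L and at least 159-fold higher at 5 µg/L, because its Cy5 spot was saturated on all 6 and all 4 arrays. At 50 µg/L the measured fold was 225 with 5 of 7 spots saturated. The 14 other probes of vtg3 also rose in each of these 6 comparisons. Averaged over 15 probes, vtg3 ratios ranged from -3.57 to -2.66 on 24 h control arrays and from 3.44 to 3.82 at 5 µg/L, and the lowest array of 0.5 µg/L stood at 0.05.

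Among the other vitellogenins, vtg7 rose by 5.37 ± 0.51 and 6.39 ± 0.51 at 5 and 50 µg/L at 24 h, and by 6.50 ± 0.52, 7.62 ± 0.59 and 7.64 ± 0.50 at the 3 doses at 96 h. With 0.5 µg/L for 24 h vtg7 measured 1.82 ± 0.51 higher, without passing the threshold (adjusted p = 0.0885). Its ratios on these 6 arrays ran from -4.91 to 1.52, against -4.52 to -2.54 on 24 h controls. The arrays therefore differed widely, which the SE, fitted over all groups, does not show. At 96 h vtg2 rose by 0.68 ± 0.17 at 5 µg/L and 0.60 ± 0.15 at 50 µg/L, calls that ended with pooled controls (0.35 and 0.27, adjusted p = 0.233 and 0.212). After 24 h at 50 µg/L vtg4 rose by 0.55 ± 0.19 (adjusted p = 0.0459), a call that ended in 11 of the 14 fits that left out 1 array. It also ended without centring (adjusted p = 0.0507), with only the arrays of the contrast (0.0931), with pooled controls (0.140) and without the low-signal arrays (0.113). In fish at 50 µg/L, vtg5 (0.34 ± 0.18 at 24 h and 0.09 ± 0.17 at 96 h), vtg6 (0.11 ± 0.17 and 0.03 ± 0.18), vtg2 at 24 h (0.05 ± 0.15) and vtg4 at 96 h (-0.14 ± 0.20) did not pass the threshold. On 24 h controls the ratios to the pool were 0.57, 0.07, 0.21 and -0.0033 for vtg2, vtg4, vtg5 and vtg6. Those of vtg3 and vtg7 were -3.42 and -3.46. The vtg6 spot was above background on 3 arrays of 50 µg/L at each time. Whether these 4 probes detect the liver transcripts is unknown, so a lack of response of these genes is not established. Over the 6 tested vitellogenins, 3 rose at 50 µg/L at 96 h (3 adjusted over the list alone, camera adjusted p = 0.00432 with an estimated correlation).

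The estrogen receptor gene esr1 (probe 5461836) rose by 3.27 ± 0.32 at 5 µg/L and 3.60 ± 0.32 at 50 µg/L at 24 h, and by 2.43 ± 0.33, 3.37 ± 0.37 and 3.07 ± 0.31 at 0.5, 5 and 50 µg/L at 96 h. These sizes are uncertain, since its spot was above background on 4 and 5 of 6 arrays at 24 h and on 4 of 6, 4 of 4 and 6 of 7 at 96 h, and is unknown for the controls. After 24 h at 0.5 µg/L esr1 differed by 0.20 ± 0.32 (adjusted p = 0.873), with its spot above background on 1 of 6 arrays. The other receptor gene esr2a fell by 0.76 ± 0.21 at 50 µg/L and 96 h (adjusted p = 0.0063) and measured -0.29 ± 0.21 at 24 h. The representative probe of esr2b differed by -0.24 ± 0.26 and -0.18 ± 0.26 at 50 µg/L at 24 and 96 h; its other probe fell by 0.74 at 96 h (adjusted p = 0.0251). Of the 7 measured genes in the list of estrogen receptors and known estrogen targets, 2 rose and 2 fell at 50 µg/L and 96 h (2 and 2 adjusted over the list alone).

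**Figure D1:**
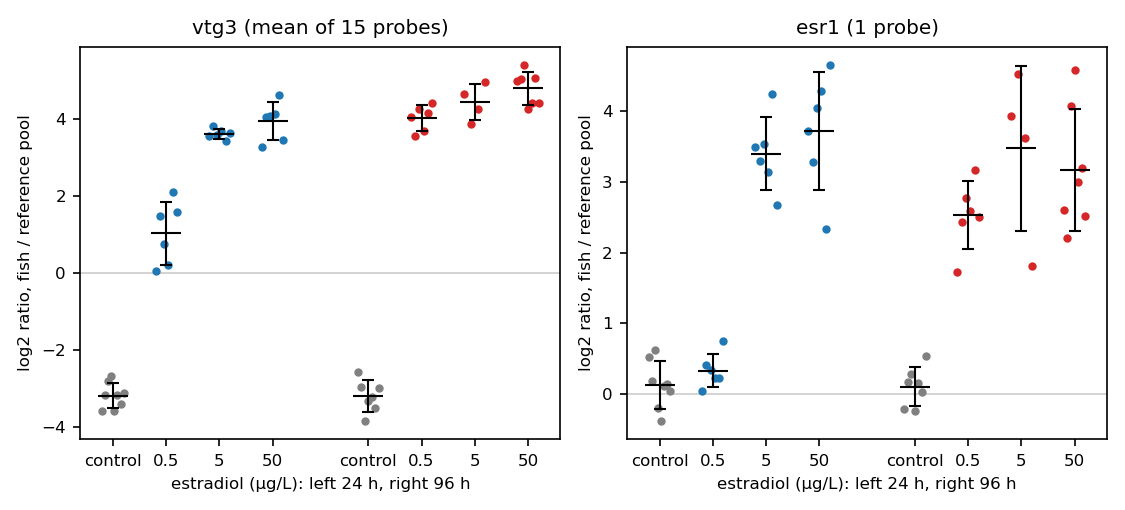
Log2 ratio of fish sample over reference pool (vertical axis) for vtg3, averaged over 15 probes, and esr1, by estradiol dose in µg/L and time; dots are arrays, horizontal bars are group means and error bars are ± 1 SD. Control arrays of vtg3 at 24 h lie between -3.57 and -2.66, and the 5 µg/L arrays between 3.44 and 3.82.

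Against the controls of the same time, 111 of 22046 probes changed at 0.5 µg/L, 1340 at 5 µg/L and 2820 at 50 µg/L at 24 h. At 96 h the counts were 716, 2778 and 3960. Camera with a preset correlation called 17 to 23 of the 37 gene lists in each comparison. Random regroupings of the same arrays called a median of 9 to 12 lists, so the p with an estimated correlation, which called 40 of 222 list tests, is given below for the called lists that are described. Not every called list is described. At 5 µg/L 8 lists passed with the estimated correlation at 24 h and 7 at 96 h, of which only some are named below.

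**Figure D2:**
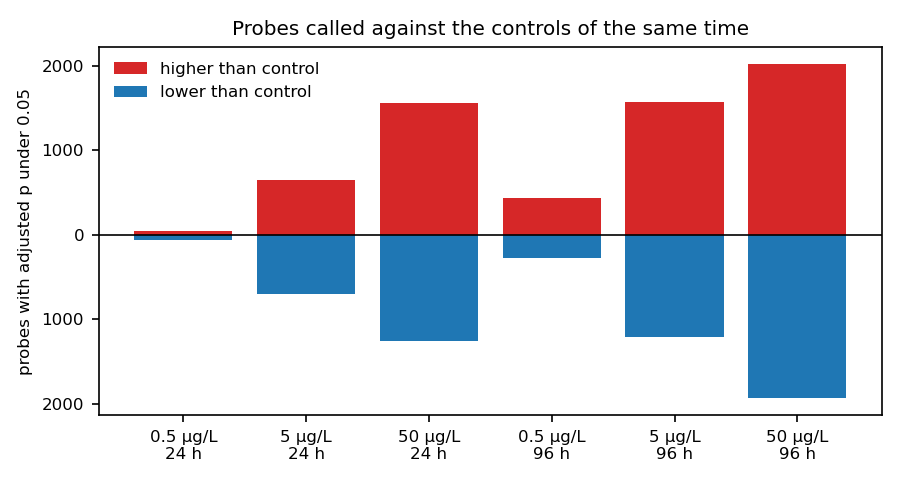
Number of probes with a limma adjusted p under 0.05 that were higher (upward bars) or lower (downward bars) than the controls of the same time, by dose and exposure time. Upward bars run from 46 probes at 0.5 µg/L and 24 h to 2025 at 50 µg/L and 96 h.

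The comparison of 50 µg/L with controls at 96 h asked which liver transcripts stand apart after the longest exposure to the highest dose (n = 7 and 7 arrays). Besides the vitellogenins, the largest measured rises of named genes were those of rtn1, a reticulon of the endoplasmic reticulum (6.26 ± 0.31, Cy5 spot saturated on 2 of 7 arrays), nots, an aspartic protease of the cathepsin D family (6.03 ± 0.26, saturated on 4 of 7), and the transcription factor gene pax9 (5.01 ± 0.37). Next came the apolipoprotein gene apoea (4.33 ± 0.69), the inflammasome adaptor gene pycard (4.23 ± 0.28) and the cytochrome P450 gene cyp2k16 (4.23 ± 0.28). The largest falls of named genes were those of hpxa, hemopexin, which binds heme in plasma (-5.04 ± 0.56), serpina7 (-4.33 ± 0.32), the terminal complement component gene c9 (-4.25 ± 0.31) and cyp1a, a detoxifying cytochrome P450 (-3.76 ± 0.29). Further falls were those of comtd1 (-3.69 ± 0.26), upp2, a uridine phosphorylase (-3.56 ± 0.33), the selenoprotein gene selenop2 (-3.49 ± 0.24) and fbp1 of gluconeogenesis (-3.36 ± 0.35, with values on 6 treated arrays). The spots of hpxa, upp2 and fbp1 were above background on 5 treated arrays. In all, 3960 probes changed, 2025 up and 1935 down. Among the rises, 16 probes that are not named here rose by 8.67 to 10.3.

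Plasma protein genes fell together at 50 µg/L and 96 h. Of 37 complement and coagulation genes, 29 fell and 2 rose (29 and 2 adjusted over the list alone, camera adjusted p = 0.00327 with an estimated correlation). Among them were serpinc1, antithrombin (-2.55 ± 0.20), cpb2 (-2.66 ± 0.26) and c8a (-2.30 ± 0.23). Of 18 acute phase and plasma transport genes, 12 fell and none rose (14 fell adjusted over the list alone, adjusted p = 0.00558 with an estimated correlation). They included hp, haptoglobin (-3.19 ± 0.32), and tdo2a (-2.11 ± 0.17), an enzyme gene that is also in the list of amino acid catabolism. Of 13 genes of the apolipoprotein list 8 fell and apoea rose (8 and 1 adjusted over the list alone, adjusted p = 0.0118 with an estimated correlation). The falls included apom (-2.48 ± 0.20), apobb.1 (-2.09 ± 0.26) and cetp (-2.67 ± 0.33), a lipid transfer protein gene that this list also holds. Of 11 hepatocyte marker genes, 10 of which are also in other lists, 9 fell (11 adjusted over the list alone, adjusted p = 0.0114 with an estimated correlation), such as hpda of tyrosine breakdown (-1.79 ± 0.26) and serpina1 (-2.49 ± 0.27).

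Of 56 xenobiotic metabolism genes 24 fell and 2 rose at 50 µg/L and 96 h (29 and 3 adjusted over the list alone, adjusted p = 0.0114 with an estimated correlation), with cyp2n13 (-2.19 ± 0.26) and gstz1 (-1.61 ± 0.22) among the falls. Of 25 fatty acid oxidation genes 16 fell (18 adjusted over the list alone, adjusted p = 0.0739 with an estimated correlation), including cpt1b (-1.87 ± 0.23) and decr1 (-2.25 ± 0.27), whose other probe did not pass. Of 34 genes of amino acid catabolism and the urea cycle 14 fell and 4 rose (15 and 5 adjusted over the list alone, adjusted p = 0.0563 with an estimated correlation). Of these, agxtb fell by 2.99 and mat2aa rose by 2.02. Of 33 genes of glycolysis, gluconeogenesis and glycogen 9 fell and 7 rose (11 and 7 adjusted over the list alone), with pygl, glycogen phosphorylase (-2.45 ± 0.22), and gys2, glycogen synthase (-1.65 ± 0.20), both lower. The median of this list was 0.04 (-0.00 with array weights), while its mean of -0.26 and camera pointed down (adjusted p = 0.239 with an estimated correlation). In the growth hormone and insulin-like growth factor list, 4 of 13 genes fell (4 adjusted over the list alone, adjusted p = 0.0707 with an estimated correlation): igf1 (-1.91 ± 0.27), igf2a (-1.59 ± 0.22), igf2b (-1.06 ± 0.21) and igfbp2a (-1.86 ± 0.21). Of 12 genes of bile acid and lipid transport 5 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.0949 with an estimated correlation), slc27a2a by -3.18 ± 0.31 and fabp1b.1 by 4.09 ± 0.62.

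Of 17 aminoacyl-tRNA synthetases 15 rose at 50 µg/L and 96 h (16 adjusted over the list alone, adjusted p = 0.0043 with an estimated correlation), such as wars1 (2.12 ± 0.21) and tars1 (1.99 ± 0.17), whose other probe did not pass. Of 73 genes of folding and secretion in the endoplasmic reticulum 48 rose and 2 fell (53 and 2 adjusted over the list alone, adjusted p = 0.0692 with an estimated correlation). Examples are the cargo receptor gene lman1 (2.72 ± 0.19) and xbp1, a transcription factor of the unfolded protein response (1.99 ± 0.18). Of 68 cytosolic ribosomal protein genes 53 rose and 1 fell (57 and 2 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). They included rpl30 (1.70 ± 0.19) and rpl29 (1.48 ± 0.19). Of the 68 probes, 47 had a spot at the top of the scanner's range on a treated array. The 1 fall was that of rps6 (-3.34 ± 0.22), whose other probes measured 0.30 and -0.42. Proteasome subunits rose in 31 of 51 cases and fell in 1 (35 and 1 adjusted over the list alone, adjusted p = 0.0838 with an estimated correlation). Translation factors rose in 28 of 67 cases and fell in 1 (34 and 2, adjusted p = 0.0568 with an estimated correlation), and ribosome biogenesis genes rose in 26 of 54 cases (31, adjusted p = 0.159 with an estimated correlation). Examples are psmc1a (1.28 ± 0.16), eif2s2 (1.45 ± 0.15) and nhp2 (1.71 ± 0.22).

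Cholesterol synthesis genes rose in 8 of 17 cases at 50 µg/L and 96 h (12 adjusted over the list alone, adjusted p = 0.35 with an estimated correlation), hmgcs1 by 1.76 ± 0.41 and dhcr7 by 1.39 ± 0.32. Of 83 genes of oxidative phosphorylation 21 rose and 2 fell (23 and 2 adjusted over the list alone, adjusted p = 0.631 with an estimated correlation), cox6a1 by 1.12 ± 0.19 among them. Of 54 DNA replication and mitosis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.7 with an estimated correlation), with cdk1 at 1.55 ± 0.23. Camera's call of this list with the preset correlation also ended after quantile normalization (adjusted p = 0.262) and with array weights (0.0637). Camera did not call the lists of oxidative stress defence (8 of 25 rose and 5 fell; 10 and 6 adjusted over the list alone), antigen presentation and interferon (4 of 22 rose and 1 fell; 4 and 1), fatty acid and triglyceride synthesis (3 of 16 rose and 5 fell; 4 and 6), or RNA splicing (13 of 60 rose; 13) in this comparison. Nor did it call markers of cholangiocytes (1 of 12 fell; 0 adjusted over the list alone), exocrine pancreas (4 of 21 rose; 4), endocrine pancreas (1 of 6 fell; 1), erythrocytes (1 of 20 rose and 2 fell; 1 and 2) and lymphocytes (1 of 8 rose and 1 fell; 1 and 1). The same held for macrophages and neutrophils (1 of 22 rose; 1), endothelium (1 of 11 rose and 2 fell; 1 and 2), stellate cells (1 of 17 rose and 2 fell; 1 and 2), intestine (0 of 11), skeletal muscle (2 of 26 rose; 2), testis (2 of 14 rose; 2 rose and 1 fell adjusted over the list alone), and ovary (1 of 21 fell; 1).

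**Figure D3:**
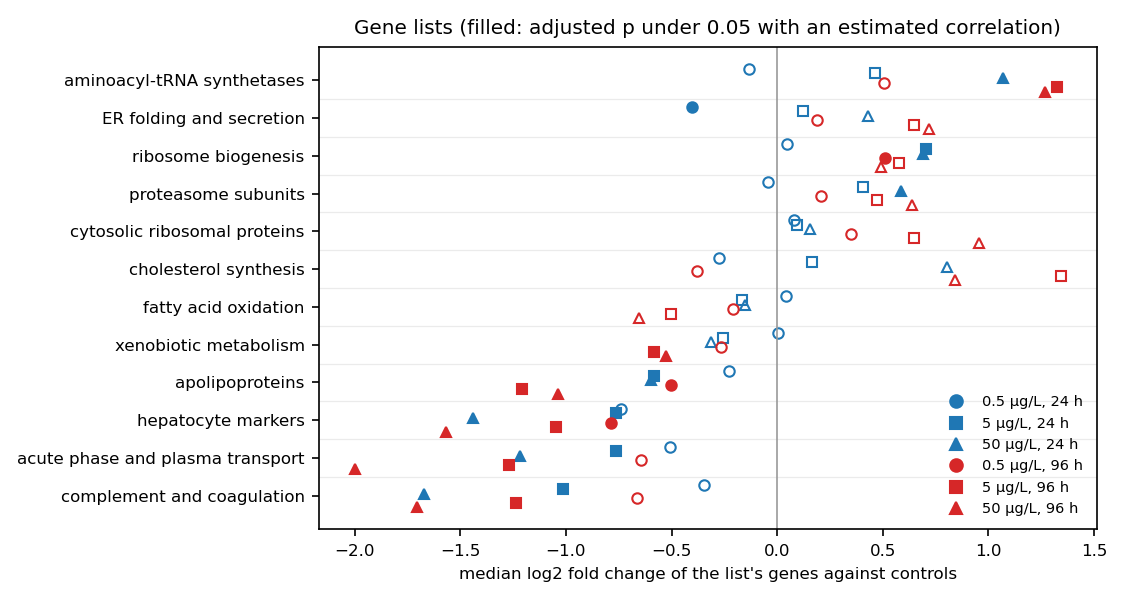
Median log2 fold change against the controls of the same time (horizontal axis) over the genes of 12 lists, by dose (symbol) and time (colour: blue 24 h, red 96 h). Filled symbols have a camera adjusted p under 0.05 with an estimated correlation; complement and coagulation medians run from -0.35 at 0.5 µg/L and 24 h to -1.70 at 50 µg/L and 96 h.

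At 24 h, 50 µg/L was compared with controls to see which responses were present early (n = 6 and 8). After vtg3 and vtg7, nots (4.69 ± 0.26), rtn1 (4.24 ± 0.32), pax9 (4.15 ± 0.38) and esr1 rose most among named genes. The fatty acid binding protein gene fabp1b.1 (3.34 ± 0.63) and apoea (3.21 ± 0.70) followed. The largest falls were those of serpina7 (-4.63 ± 0.33), c9 (-4.16 ± 0.31), the central complement gene c3a.2 (-3.56 ± 0.33) and apoeb (-3.55 ± 0.38). Next were the mitochondrial carrier gene slc25a48 (-3.44 ± 0.39), c3a.1 (-3.34 ± 0.33), the heme oxygenase gene hmox1b (-3.32 ± 0.46) and c3a.3 (-3.28 ± 0.37). In all 1564 probes rose and 1256 fell. Without the 5 arrays of low signal, an alternative added after seeing the data, the count was 1857, with 944 up and 913 down.

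By list, 27 of 37 complement and coagulation genes fell at 50 µg/L and 24 h (28 adjusted over the list alone, adjusted p = 0.00117 with an estimated correlation). So did 12 of 18 acute phase genes (13 fell and 1 rose adjusted over the list alone, adjusted p = 0.00713 with an estimated correlation) and 9 of 11 hepatocyte markers (9, adjusted p = 0.0104 with an estimated correlation). Examples are cfb (-2.56 ± 0.23), serpina1 (-2.37 ± 0.27) and fgb, fibrinogen beta (-2.34 ± 0.29). Of 13 genes of the apolipoprotein list 7 fell and 1 rose (8 and 1 adjusted over the list alone, adjusted p = 0.0114 with an estimated correlation). Glycolysis and glycogen genes fell in 11 of 33 cases (14 fell and 2 rose adjusted over the list alone, adjusted p = 0.0204 with an estimated correlation), with pygl at -2.07 ± 0.22 and eno3 at -1.59 ± 0.22. In the growth hormone list 7 of 13 fell (7 adjusted over the list alone, adjusted p = 0.0284 with an estimated correlation), igf1 by -1.30 ± 0.28. Aminoacyl-tRNA synthetases rose in 15 of 17 cases (15 adjusted over the list alone, adjusted p = 0.00701 with an estimated correlation) and ribosome biogenesis genes in 37 of 54 (40 rose and 1 fell adjusted over the list alone, adjusted p = 0.0112 with an estimated correlation), with nhp2 at 2.00 ± 0.22. Proteasome subunits rose in 31 of 51 cases (36 adjusted over the list alone, adjusted p = 0.0491 with an estimated correlation), and translation factors rose in 27 of 67 and fell in 1 (34 and 3, adjusted p = 0.0394 with an estimated correlation). Of the endoplasmic reticulum list 30 of 73 rose and 3 fell (33 and 5 adjusted over the list alone, adjusted p = 0.236 with an estimated correlation), lman1 by 2.12 ± 0.19. Among 60 genes of RNA splicing 11 rose (16 adjusted over the list alone, adjusted p = 0.41 with an estimated correlation), snrpe by 1.01 ± 0.16. Endothelial markers fell in 2 of 11 cases (2 adjusted over the list alone, adjusted p = 0.111 with an estimated correlation).

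At 5 µg/L and 96 h (n = 4 and 7) vtg7 and vtg3 rose most among named genes, followed by rtn1 (6.14 ± 0.37, Cy5 spot saturated on 1 of 4 arrays), nots (5.90 ± 0.31, saturated on 3 of 4), pax9 (5.62 ± 0.44), the transporter gene slc22a23 (4.16 ± 0.47), cyp2k16 (4.07 ± 0.33) and pycard (4.06 ± 0.33). The falls were led by hpxa (-6.09 ± 0.66), c9 (-3.79 ± 0.36) and the liver fatty acid binding protein gene fabp10a (-3.59 ± 0.55). Also lower were adh8a (-3.59 ± 0.52), comtd1 (-3.58 ± 0.30), tgfbi (-3.29 ± 0.29), upp2 (-3.26 ± 0.38) and pno1 (-3.25 ± 0.39). For tgfbi and upp2 the spot was above background on 2 of 4 treated arrays. The other probes of adh8a and pno1 measured -0.15 and 0.48 and did not pass. In all 1569 probes rose and 1209 fell. Aminoacyl-tRNA synthetases rose in 15 of 17 cases (15 adjusted over the list alone, adjusted p = 0.00278 with an estimated correlation), with tars1 at 2.06 ± 0.20, and 12 of 17 cholesterol synthesis genes rose (13, adjusted p = 0.0809 with an estimated correlation), with nsdhl at 1.70 ± 0.27. The endoplasmic reticulum list rose in 37 of 73 cases and fell in 2 (48 and 2 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation). Complement and coagulation genes fell in 25 of 37 cases and rose in 1 (27 and 1 adjusted over the list alone, adjusted p = 0.00787 with an estimated correlation), and xenobiotic metabolism genes fell in 24 of 56 and rose in 3 (25 and 3, adjusted p = 0.0183 with an estimated correlation), cyp1a by -3.04 ± 0.34.

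At 5 µg/L and 24 h (n = 6 and 8) 645 probes rose and 695 fell. Among named genes the rises were led by vtg3 and vtg7, with rtn1 (3.75 ± 0.32), nots (3.41 ± 0.26), esr1, pax9 (3.22 ± 0.38), the chitinase gene chia.1 (2.81 ± 0.66) and apoea (2.62 ± 0.70). Without 5 µg/L replicate 6 the call of apoea ended, at 2.17. The falls were led by hmox1b (-2.76 ± 0.46), c9 (-2.57 ± 0.31), apoeb (-2.54 ± 0.38), c3a.2 (-2.49 ± 0.33), hp (-2.24 ± 0.33), c3a.3 (-2.21 ± 0.37), the steroid dehydrogenase gene hsd17b3 (-2.18 ± 0.26) and upp2 (-2.16 ± 0.33). Ribosome biogenesis genes rose in 32 of 54 cases (37 adjusted over the list alone, adjusted p = 0.00327 with an estimated correlation), such as bysl (1.44 ± 0.20). Complement and coagulation genes fell in 22 of 37 (28 adjusted over the list alone, adjusted p = 0.00432 with an estimated correlation). Of 16 genes of fatty acid and triglyceride synthesis 7 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 0.0271 with an estimated correlation), with elovl6 at -1.84 ± 0.33 and dgat2 at -1.13 ± 0.20. DNA replication and mitosis genes rose in 12 of 54 cases (20 adjusted over the list alone, adjusted p = 0.164 with an estimated correlation), including mcm6 (1.21 ± 0.23), and intestine markers in 2 of 11 (5, adjusted p = 0.257 with an estimated correlation). The probe count was 2368 with array weights and 2226 with the controls of both times pooled.

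At 0.5 µg/L and 96 h (n = 6 and 7) 440 probes rose and 276 fell. After vtg3 and vtg7, nots (4.67 ± 0.27), pax9 (3.99 ± 0.39), rtn1 (3.59 ± 0.33), cyp2k16 (3.31 ± 0.29), nubpl, an iron-sulfur cluster assembly gene (3.05 ± 0.28), and pycard (3.01 ± 0.29) rose most among named genes. Lower were serpina7 (-1.61 ± 0.34, Cy5 spot saturated on 1 of 6 arrays), the sugar transporter gene slc2a5 (-1.65 ± 0.30, other probe -0.60 and not called), upp2 (-1.54 ± 0.34), hsd17b3 (-1.47 ± 0.27), slc22a2 (-1.46 ± 0.27), hpxa (-2.14 ± 0.58) and cyp2aa4 (-1.73 ± 0.50). Ribosome biogenesis genes rose in 19 of 54 cases (31 adjusted over the list alone, adjusted p = 0.00963 with an estimated correlation), translation factors in 12 of 67 (14, adjusted p = 0.0428 with an estimated correlation) and aminoacyl-tRNA synthetases in 6 of 17 (10, adjusted p = 0.0559 with an estimated correlation). Genes of the apolipoprotein list fell in 3 of 13 cases (7 adjusted over the list alone, adjusted p = 0.0253 with an estimated correlation) and hepatocyte markers in 2 of 11 (10, adjusted p = 0.0497 with an estimated correlation). Adjusted over the lists of this comparison alone, translation factors and hepatocyte markers did not pass (0.0599 each). No exocrine pancreas marker passed over all probes, while 3 of 21 rose adjusted over the list alone (median 0.97, adjusted p = 0.276 with an estimated correlation). The probe of rgrb measured -1.45 ± 0.38 (adjusted p = 0.0195). The calls of hpxa, cyp2aa4 and rgrb ended without 1 array in 4, 9 and 3 of 13 fits; without 0.5 µg/L replicate 6 their values were -1.64, -1.16 and -1.27. All 3 calls also ended after quantile normalization, and that of cyp2aa4 with only the arrays of the contrast, trended robust eBayes and array weights. The Cy5 spot of rgrb was saturated on all 6 treated arrays and its other probe measured -0.19 and was not called, so a fall of this gene is not established. Counts were 1618 with array weights, 463 and 441 without 0.5 µg/L replicates 3 and 6, 415 without control replicate 2, and split 419 up and 153 down after quantile normalization.

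In the comparison of 0.5 µg/L with controls at 24 h (n = 6 and 8) vtg3 rose most among named genes. The next were those of btg2, an antiproliferative gene (1.36 ± 0.29), elf3 (1.15 ± 0.26), selenoh (0.95 ± 0.23), ypel3 (0.92 ± 0.21), the oxygen sensor gene egln1b (0.89 ± 0.19), gsta.1 (0.85 ± 0.21) and tk1, thymidine kinase (0.76 ± 0.19; other probe 0.16). The falls were hmox1a (-2.22 ± 0.55), rgs2 (-1.97 ± 0.49), the endoplasmic reticulum chaperone gene calr3b (-1.71 ± 0.37, with 1 other probe at 0.06), hp (-1.31 ± 0.33), cyb5b (-1.24 ± 0.27), manf (-1.19 ± 0.28), ugt5a2 (-1.12 ± 0.24) and itpkcb (-1.12 ± 0.28). Of 73 genes of the endoplasmic reticulum list 4 fell (33 adjusted over the list alone; median -0.40, adjusted p = 0.0259 with an estimated correlation, and 0.0670 when adjusted over the lists of this comparison alone). In all 46 probes rose and 65 fell. Of the 46 rises, 15 were probes of vtg3 and 22 were probes without a name here. By representative probe 9 named genes rose.

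Replicate 2 of this group stood apart, with r of 0.592 to the rest of its group and an ovary and oocyte marker median 2.80 above the other 5 arrays. No ovary marker passed in the comparison (0 of 21 over all probes and adjusted over the list alone, adjusted p = 0.258 with an estimated correlation), and the list median of 0.46 was 0.06 without that array. Without it the endoplasmic reticulum list median was -0.38, and 1 member fell. Of the 16 genes named above, vtg3 and egln1b kept their calls in every fit that left out 1 array, and 14 lost theirs in at least 1. Without replicate 2 the calls of selenoh (0.71), ypel3 (0.86), gsta.1 (0.84), tk1 (0.59), rgs2 (-1.82), calr3b (-1.55), hp (-0.78), ugt5a2 (-0.91), itpkcb (-1.03) and hmox1a (adjusted p = 0.0916) ended. The calls of btg2 (1.17 without replicate 3), elf3 (0.92 without replicate 5), cyb5b (-1.11) and manf (-1.04) also ended. With only the arrays of the contrast btg2, elf3, selenoh, egln1b, gsta.1, tk1, hmox1a, rgs2, hp, manf, ugt5a2 and itpkcb lost their calls. With pooled controls selenoh, ypel3, gsta.1, tk1, hmox1a, rgs2, calr3b, cyb5b, manf and itpkcb did, after quantile normalization tk1, hmox1a, hp and manf, with trended robust eBayes tk1, hmox1a and rgs2, with array weights tk1, hmox1a, rgs2 and hp, and with a replicate block ypel3, gsta.1, tk1 and itpkcb. The probe count of 111 was 70 (40 up and 30 down) without replicate 2, 67 without replicate 5, and 63 and 178 without control replicates 1 and 4. It was 44 (33 up and 11 down) with only the arrays of the contrast, 342 (106 up and 236 down) with array weights, and 64 up and 42 down with pooled controls.

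Besides the endoplasmic reticulum list, only vitellogenins kept camera's call at 0.5 µg/L and 24 h with the estimated correlation (adjusted p = 0.00787 with an estimated correlation). Adjusted over the 37 lists of this comparison alone, vitellogenins kept it (0.0207) and the endoplasmic reticulum list did not (0.0670). Of the 6 tested vitellogenins only vtg3 passed over all probes, and the list median was 0.06. This list call therefore does not show a rise of the vitellogenins as a family. Acute phase genes fell in 2 of 18 cases (5 adjusted over the list alone, adjusted p = 0.102 with an estimated correlation), among them tdo2a, also in the amino acid catabolism list, by -0.81 ± 0.17. Hepatocyte markers fell in 1 of 11 cases, fgg, fibrinogen gamma, by -1.01 ± 0.25 (7, adjusted p = 0.0645 with an estimated correlation). Without replicate 2 no member of either list fell, and the medians of -0.51 and -0.74 were -0.39 and -0.57. After quantile normalization camera's calls with the preset correlation ended for complement (adjusted p = 0.873), acute phase (0.262) and hepatocyte genes (0.0875). DNA replication and mitosis genes rose in 1 of 54 cases (3 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). The median of this list was 0.31, and 0.11 without replicate 2, whose members lay a median of 1.27 above the other 5 arrays. No testis, intestine or endocrine pancreas marker passed over all probes, while 4 of 14, 3 of 11 and 4 of 6 rose adjusted over the list alone (adjusted p = 0.257, 0.206 and 0.174 with an estimated correlation).

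Whether the effect of a dose differed between 96 and 24 h was tested as a difference of differences. At 0.5 µg/L the effect was larger at 96 h for vtg7 (4.68 ± 0.73), nots (4.16 ± 0.38), fkbp11, a prolyl isomerase of the endoplasmic reticulum (3.24 ± 0.46), and pax9 (3.12 ± 0.54). It was lower for diabloa (-1.91 ± 0.50), cyp2n13 (-1.52 ± 0.38), ypel3 (-1.41 ± 0.30) and smim14 (-1.37 ± 0.26). In all 154 probes had a higher and 13 a lower effect at 96 h. Between the control groups fkbp11 (adjusted p = 0.00553), cyp2n13 (0.0013) and smim14 (0.0162) changed in the opposite direction. The calls of diabloa and cyp2n13 ended in 18 and 15 of the 27 fits without 1 array, with only the arrays of the contrast and with a replicate block, and that of diabloa after quantile normalization, with a looser filter and with trended robust eBayes. The count of 167 was 444 with array weights.

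At 5 µg/L 213 probes had a higher and 68 a lower effect at 96 h. The higher effects included nots (2.49 ± 0.41, with its Cy5 spot saturated on 3 of the 4 arrays at 96 h), the fatty acid desaturase gene scd (2.48 ± 0.61), pycard (2.39 ± 0.44) and pax9 (5.28-fold). The lower ones were hpxa (-4.83 ± 0.87), fabp10a (-2.95 ± 0.72), tgfbi (-2.86 ± 0.38) and adh8a (-2.55 ± 0.68; other probe -0.15). Without 5 µg/L 96 h replicate 2 the count of 281 was 161, pax9 (adjusted p = 0.0767) and fabp10a (-2.73) lost their calls, and adh8a measured -2.13. The calls of pax9 (adjusted p = 0.0588) and fabp10a (-2.77) also ended without replicate 1, that of scd without replicate 4 (2.14), and that of adh8a in 17 of 25 such fits. After quantile normalization pax9 (1.76) and adh8a lost theirs, as did adh8a with only the arrays of the contrast, trended robust eBayes and array weights. Between the control groups tgfbi changed by 1.18 in the opposite direction.

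With the highest dose 38 probes had a higher effect at 96 h and 5 a lower one. This count of 43 was 344 (190 and 154) without 96 h replicate 4 and 24 h replicate 5, a setting chosen after seeing that each resembled the other time. Among the 42 pairs of 1 array from each time, no other gave over 121 when left out. The higher ones included the tetraspanin gene cd63 (3.17 ± 0.49), the lysosomal protease gene ctsla (2.70 ± 0.50), the ferritin gene fthl31 (2.25 ± 0.52) and ntd5 (2.18 ± 0.49). The lower ones were cyp4v2a (-2.02 ± 0.43) and dhtkd1 (-1.43 ± 0.32). For cyp4v2a (1.74), ntd5 (-1.94), cd63 (-1.71) and ctsla (-1.55) the control groups themselves changed between times in the opposite direction. Leaving out 1 array ended the calls of fthl31, ntd5, cyp4v2a and dhtkd1 in 16, 13, 7 and 15 of 28 fits, and those of cd63 and ctsla in none. With only the arrays of the contrast fthl31, ntd5 and dhtkd1 lost their calls, with a replicate block fthl31 and dhtkd1, with array weights ntd5, and without the low-signal arrays cyp4v2a. The count was also 22 with only the arrays of the contrast, 260 with array weights and 148 without the 5 low-signal arrays. It changed by over 1.5 times without any of 16 arrays: 50 µg/L 96 h replicates 1 (21), 3 (17), 4 (135), 5 (27) and 6 (8), and 24 h replicates 1 (14), 2 (11), 4 (19), 5 (124) and 6 (6). The others were 96 h controls 1 (67), 2 (21), 3 (16) and 6 (16) and 24 h controls 1 (18) and 2 (28).

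Untreated males gave the background of these time differences. Between 96 and 24 h controls (n = 7 and 8) 64 probes were higher and 160 lower at 96 h. Higher were cyp4v2a (1.74 ± 0.29), the sterol synthesis genes ebp (1.69 ± 0.41) and hmgcs1 (1.61 ± 0.40), and apoa4b.1 (1.54 ± 0.36). Lower were slc16a9a (-3.47 ± 0.54), odc1 of polyamine synthesis (-2.01 ± 0.34), ntd5 (-1.94 ± 0.33) and rgs2 (-1.94 ± 0.47). Leaving out 1 control array ended the calls of ebp, hmgcs1, apoa4b.1 and rgs2 in 4, 7, 2 and 5 of 15 fits. After quantile normalization, and with only the control arrays, ebp, hmgcs1 and rgs2 lost theirs. With a replicate block ebp, hmgcs1 and apoa4b.1 did, and with array weights rgs2. The count of 224 was 395, 98, 137 and 114 without 96 h controls 1, 2, 3 and 6, 98 and 141 without 24 h controls 1 and 2, 125 after quantile normalization and 74 with only the control arrays.

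The doses were also compared directly between treated fish, from scanner brightness. At 24 h (n = 6 and 6) 50 µg/L exceeded 0.5 µg/L for vtg7 (4.72 ± 0.57), nots (4.20 ± 0.32), the phospholipid enzyme gene pisd (4.01 ± 0.40) and esr1 (3.67 ± 0.35). The esr1 spot was above background on 1 of the 6 arrays of 0.5 µg/L and 5 of the 6 of 50 µg/L, so the size of its difference is uncertain. It lay below 0.5 µg/L for serpina7 (-3.52 ± 0.39), c9 (-3.41 ± 0.37), hpxa (-3.26 ± 0.66) and cyp1a (-3.19 ± 0.24; above background on 3 of the 6 arrays of 50 µg/L). At 0.5 µg/L the Cy5 spots of serpina7, c9 and hpxa were saturated on 2, 1 and 2 of 6 arrays. In all 1358 probes were higher and 851 lower, and the split was 1109 and 1103 with median centring instead of loess. The count of 2209 was 3585 with array weights and 1406 without the 5 low-signal arrays.

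At 96 h (n = 7 and 6) 541 probes were higher and 501 lower at 50 than at 0.5 µg/L. Higher were apoea (3.52 ± 0.77), pisd (2.98 ± 0.39), rtn1 (2.64 ± 0.36, Cy5 spot saturated on 2 of 7 arrays) and the amino acid transporter gene slc43a1a (2.62 ± 0.25; other probe 2.43). Lower were hpxa (-3.11 ± 0.64), c9 (-2.91 ± 0.36), gatm of creatine synthesis (-2.90 ± 0.35; other probe -0.10) and cyp1a (-2.90 ± 0.23). The spots of hpxa and gatm were above background on 5 of the 7 arrays of 50 µg/L, and that of c9 was saturated on 1 of the 6 arrays of 0.5 µg/L. With median centring instead of loess 371 were higher and 543 lower, and array weights gave 1615 probes.

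In 9 pairs the responses to different doses and times were set against each other across the 22046 probes, which are not independent replicates. Doses at the same time share their controls, which alone gives a correlation above 0. At 24 h Pearson's r was 0.895 between 5 and 50 µg/L, 0.602 between 0.5 and 5 µg/L and 0.519 between 0.5 and 50 µg/L. The same pairs gave 0.427, 0.433 and 0.431 simulated for unchanged groups and 0.788, 0.450 and 0.406 observed with the controls split. At 96 h Pearson's r was 0.913, 0.823 and 0.827 for the same pairs, against 0.422, 0.411 and 0.479 simulated and 0.775, 0.675 and 0.653 with split controls. Spearman's r at 96 h was 0.785, 0.681 and 0.703, against 0.400, 0.389 and 0.454 simulated. The covariances at 24 h were 0.229, 0.0877 and 0.0938 against simulated values of 0.0204, 0.0205 and 0.0206, and at 96 h 0.373, 0.236 and 0.240 against 0.0229, 0.0230 and 0.0231. Between 5 and 50 µg/L at 96 h 1233 rises and 1012 falls were shared, against 144 and 106 for independent lists, and at 24 h 568 and 610 against 45.8 and 39.6. Shared controls can raise these overlaps too, so independent lists are too low a background within a time. Between times, which share no arrays, Pearson's r was 0.459, 0.702 and 0.802 at 0.5, 5 and 50 µg/L, and Spearman's r 0.206, 0.399 and 0.556. At 50 µg/L 941 rises and 768 falls were shared, against 144 and 110 for independent lists. At 0.5 µg/L 34 of the 46 rises and 8 of the 65 falls at 24 h recurred at 96 h, against 0.918 and 0.814 for independent lists.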

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

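The tests of an untreated male, of weak signal, of brightness as the whole cause and of the counts without 5 low-signal arrays were chosen after the results were seen, as was the count without 2 arrays that resembled the other time, and the others were written before their values were computed. Random regroupings of the same arrays served as the background of every count, 100 per comparison with the real grouping included. In 1 of 100 regroupings, the real one, as many probes were called for each of the 6 estradiol comparisons, the 3 differences between times and the 2 comparisons of doses, and in 2 of 100 for the controls at 96 against 24 h. For the differences between times, treated and control arrays were mixed within each time. The background there is no effect at either time, so it cannot show that an effect differed between times. At 50 µg/L the highest other regrouping called 41 probes, against 43. With the preset correlation, as many lists were called in 16, 7 and 11 of 100 regroupings at 0.5, 5 and 50 µg/L at 24 h, and in 3, 22 and 7 at 96 h. With an estimated correlation, a test added after those values were seen, the numbers were 5, 1 and 2 at 24 h and 2, 1 and 1 at 96 h, for 1, 12 and 13 and for 3, 7 and 7 lists called over the lists of 1 comparison. At 5 or more of 100, chance is not excluded for the lists of 0.5 µg/L at 24 h with either correlation. With the preset correlation it is not excluded for the other comparisons either, except 0.5 µg/L at 96 h. Without the 5 low-signal arrays 50 µg/L changed 1857 probes at 24 h and 3633 at 96 h, above the highest other regroupings of the arrays left (174 and 1171). The response at both times therefore does not rest on the low-signal arrays alone. With all arrays the counts were 2820 and 3960, and the test cannot tell whether low signal contributed to them.

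Replicate 2 of 0.5 µg/L at 24 h correlated with the rest of its group at r of 0.592, against 0.855 for the next array, and its ovary and oocyte marker median was 0.92 against -1.37 for the next. An untreated male under this label is argued against by its mean vtg3 ratio of 1.48, far above the highest 24 h control (-2.66). Weak signal is argued against by 90.1% of Cy5 spots above background, close to the group median of 90.0%. RNA of another tissue could be the cause, since ovary and oocyte markers lay 2.80 above the other 5 arrays, where the highest other array reached 0.01. The egg coat genes zp3 (5.96) and zp3b (5.24) and the cyclin gene ccnb1 (5.75) were higher by those log2 amounts, which is consistent with ovary RNA in the sample (marker median 2.80 higher), whether from a female fish or from carry-over.

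Cytosolic ribosomal protein genes had a median of 0.96 at 50 µg/L and 96 h, and their probes are among the brightest. Brightness could account for part of it, since 10000 lists of other genes matched on Cy3 brightness had a middle median of 0.31. The highest of those lists reached 0.66, below the ribosomal median. This cannot exclude brightness as the whole cause, because the lists were matched in broad bins and drawn gene by gene. Of the 68 ribosomal probes 47 had a spot at the top of the scanner's range, and genes of a list can move together. Spots at the top of the scanner's range stay open as a part of the cause, with a median of 0.50 for the 21 probes without such a spot. Low signal is argued against by a median of 1.15 without the 5 low-signal arrays.

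Responses to 50 µg/L ran opposite to the difference of untreated males from the pool of both sexes, with control and treated arrays taken from different times. Across 22046 probes, which are not independent replicates, r was -0.425 (Spearman -0.369) between 24 h controls and the 96 h response and -0.306 (Spearman -0.204) between 96 h controls and the 24 h response. A shift of male liver toward the female part of the pool would give such values and is consistent with r of -0.425, though in controls 81.0% and 76.0% of the falls lay above the pool (51.7% and 51.2% of all probes) and only 56.1% and 57.3% of the rises below it (48.3% and 48.8%). Narrower ratios on low-signal arrays as the whole cause are argued against by r of -0.432 and -0.223 without those arrays. For the 24 h response r weakened from -0.306 to -0.223, so a contribution of these arrays stays open there. Narrower ratios on the other treated arrays were not tested. Regulation by estradiol of genes unrelated to sex that happen to be low or high in males could also contribute to r of -0.306, and no female arrays were available to separate it.

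Other values stood apart without a test of their cause, except that an exchange of labels is taken up at the end for 2 arrays of 50 µg/L. Over 162 groups of values from 21 measures, 9 lay far from the rest of their group, against 8.1 expected by chance. Replicate 5 of 50 µg/L at 24 h correlated with its group at r of 0.847, against 0.902 for the next array. The share of missing probes was 18.2% on 24 h control replicate 3, against 7.89% for the next. It was 10.8% on 5 µg/L 24 h replicate 3, against 3.60%, and 24.7% on 50 µg/L 96 h replicate 3, against 7.87%. Median Cy3 brightness was 942 on 5 µg/L 24 h replicate 2, against 628. On 0.5 µg/L 24 h replicate 4, 66.5% of Cy5 spots lay above background, against 88.1%. The ovary and oocyte marker median was -2.75 on 0.5 µg/L 96 h replicate 2, against -1.84 for the next. The response differed between 96 and 24 h for 167 probes at 0.5 µg/L, 281 at 5 µg/L and 43 at 50 µg/L. Replicate 4 of 50 µg/L at 96 h correlated at r of 0.925 with the 24 h and 0.862 with the 96 h arrays of its dose, replicate 5 at 24 h at 0.890 with the 96 h and 0.847 with the 24 h arrays, and the count without both was 344.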

How the results depend on the processing

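The settings without the 5 low-signal arrays or without 1 array of each time at 50 µg/L, list medians without 1 array and list differences between times were chosen after the results were seen, as was the choice to put uncalled vitellogenin and receptor values through these settings only at 50 µg/L, and to give single list values only where called. Of named genes called, 339 of 340 kept the call without centring, 338 of 356 after quantile normalization, 355 with a looser filter, 346 of 346 with complete probes or without dim ones, 347 with trended robust eBayes, 327 with only the arrays of the contrast, 346 with array weights, 335 with replicate numbers as a block, 286 of 310 with pooled controls and 248 of 265 without low-signal arrays. All 16 from the dose comparisons kept it under other background and loess settings. Over all omissions of 1 array 4856 calls were kept and 317 lost. These genes were mostly picked for large changes or small p, so the shares do not describe the other called probes. They also differ between comparisons: at 0.5 µg/L and 24 h 14 of 16 genes lost the call in at least 1 such fit. Camera called 119 list shifts, and 119, 107, 111, 116 and 119 of them without centring, after quantile normalization, with array weights, with a replicate block and with the mean over probes. Of 103 list shifts not called, 0, 6, 1, 2 and 3 gained a call under the same settings. Replicate numbers did not pair arrays (13 of 67 same-number pairs had r over 0.1). Probe counts that moved over 1.5 times follow, with the lowest and highest without 1 array where either did. For 0.5 µg/L and 24 h 111 was 44 with only the arrays of the contrast, 342 with weights, and 63 and 178 without control replicates 1 and 4. At 5 µg/L and 24 h 1340 was 2368 with weights and 2226 with pooled controls, and at 50 µg/L and 24 h 2820 was 1857 without low-signal arrays. For 0.5 µg/L and 96 h 716 was 1618 with weights, 415 without control replicate 2 and 942 without treated replicate 2. Between times, 167 at 0.5 µg/L was 444 with weights. At 5 µg/L 281 was 161 and 345 without 96 h replicates 2 and 4. For 50 µg/L 43 was 22 with only its arrays, 260 with weights, 24 with a block, 148 without low-signal arrays, 344 without 96 h replicate 4 and 24 h replicate 5, 6 without 24 h replicate 6 and 135 without 96 h replicate 4. Between controls 224 was 125 after quantile normalization, 74 with only the controls, and 98 and 395 without 96 h replicates 2 and 1. Between doses at 24 h 2209 was 3585 with weights and 1406 without low-signal arrays, and at 96 h 1042 was 1615 with weights. Values that changed sign were small. For vtg2 the value of 50 µg/L at 24 h was -0.0203 with a block and -0.0353 to 0.130 without 1 array, vtg6 at 96 h -0.0945 to 0.161, and vtg4 at 96 h 0.0580 with pooled controls. The median of estrogen receptors and known hepatic estrogen targets at 0.5 µg/L and 96 h was 0.0340 after quantile normalization, and that of glycolysis, gluconeogenesis and glycogen at 50 µg/L and 96 h -0.00119 with weights.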

Other observations

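The differences between times of whole lists and the position of single arrays between the times were tested after the data were seen. At 0.5 µg/L the median of 73 endoplasmic reticulum genes was 0.72 higher in the 96 h than in the 24 h response, with 8 members called over all probes and 38 over the list alone (adjusted p = 0.0512 with an estimated correlation). Aminoacyl-tRNA synthetases were 0.76 higher, with 3 called over all probes and 12 over the list alone (adjusted p = 0.0512 with an estimated correlation). Ribosome biogenesis genes were 0.42 higher (4 and 18 called, adjusted p = 0.203 with an estimated correlation). With 50 µg/L ribosomal proteins were 0.79 higher at 96 h, with 0 called over all probes and 36 over the list alone (adjusted p = 0.363 with an estimated correlation). Exocrine pancreas markers were 0.92 higher at 50 µg/L and 0.55 higher at 0.5 µg/L, with 0 of 21 called (adjusted p = 0.671 and 0.795 with an estimated correlation). At 5 µg/L aminoacyl-tRNA synthetases were 0.90 higher (6 and 13 called, adjusted p = 0.0512 with an estimated correlation) and cholesterol synthesis genes 1.01 higher (1 and 9 called, adjusted p = 0.284 with an estimated correlation). Further lists passed with the preset correlation, and no list difference at any dose passed the threshold of 0.05 with an estimated one.

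The first hypothesis is that at the lowest dose yolk precursor RNA rises before the secretory machinery that handles the protein. In the measured data vtg3 rose by 4.50 at 0.5 µg/L and 24 h while 4 of 73 endoplasmic reticulum genes, among them calr3b and manf, fell and none rose (adjusted p = 0.0259 with an estimated correlation, 0.0670 when adjusted over the lists of this comparison alone), and at 96 h 11 rose and none fell (adjusted p = 0.333 with an estimated correlation). The calls of calr3b and manf ended in 1 and 6 of the 14 fits without 1 array and with pooled controls. A time course between 24 and 96 h with measurement of vtg3, lman1, ssr1 and calr3b in single fish would test the order, and without replicate 2 the list median at 24 h was -0.38 while 1 of 73 genes fell.

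The second hypothesis is that part of the response to 50 µg/L is a move of male liver toward the female pattern. It could be tested by arrays of untreated female liver against the same pool, where genes that fell by estradiol in males, such as c9, serpina7 and cyp1a, should be lower in females. The value of r of -0.425 between 24 h controls and the 96 h response does not separate this from effects unrelated to sex.

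The third hypothesis is that the labels of replicate 4 of 50 µg/L at 96 h and replicate 5 of 50 µg/L at 24 h were exchanged. Each array of this dose was placed between the times (0 at 24 h and 1 at 96 h) over the probes that differed between the treated groups without it and without these 2. The 96 h array scored 0.0486, below the highest other 24 h array (0.359), and the 24 h array scored 0.875, above the lowest other 96 h array (0.648), which is consistent with an exchange. The 24 h array had the highest averaged vtg3 ratio (4.63) and the lowest esr1 ratio (2.33) of its group, and the 96 h array had the lowest vtg3 (4.27) and the highest esr1 (4.58) of its own. The order of vtg3 is uncertain, since the Cy5 spot of its representative probe was saturated on 3 arrays of this dose at 24 h and 5 at 96 h. Fish that responded faster or slower than others could give the score of 0.0486 too and were not tested. Both arrays had low signal (57.7% of Cy5 spots above background at 96 h and 38.5% at 24 h), as had the 96 h array at 0.648 (26.4%). Low signal was not tested as a cause of the scores. With both arrays kept as labelled the count of 43 probes between times at 50 µg/L, 344 without them, may understate the difference. Leaving out arrays picked for resembling the other time tends to raise that count by itself.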
